A study of Mus musculus with 5 samples.

How the data were processed

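Messenger RNA of mouse mesenchymal stem cells was sequenced as single-end reads of 75 bp on an Illumina NextSeq instrument from libraries of a stranded kit, per the labels' protocols. STAR 2.5, featureCounts 1.5.2 and edgeR appear in the submitters' processing notes, without a stated role or order, and the genome build and annotation the authors used were not given in the sources used here. Whether counting used the strand was not stated either, so values of overlapping and antisense genes are uncertain. Such genes were neither marked nor left out. The deposited table gives 12621 genes by Ensembl identifier in 5 columns, and its values are a signal, namely gene read counts divided by a library size and brought to the scale of CPM by the authors. Column totals ran from 931660 to 1052926, which is not plain CPM. Each column's values were whole multiples of the value of 1 read, and whole reads within 0.02 of a read were recovered for 100% of values. Recovered totals ran from 13605555 to 26658725 reads. The library sizes implied by the columns matched TMM-scaled sizes computed with edgeR from these reads, with ratios that varied by 5.38e-06%, so the deposited scaling was that of TMM. The lowest maximum of any gene over the libraries was 0.984, so lower genes were not analysed here.

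Column names gave the group of each library and no replicate number of the sample titles, and libraries were therefore used as unnumbered members of their group. Gene symbols were those of the deposited table, in which 3 symbols stood on 2 rows each. Coordinates came from GENCODE M21 (GRCm38) by Ensembl identifier, which matched 12607 genes and left 14 without coordinates. Genes of the lists whose symbol was absent were looked up by an older name, which matched 3 genes.

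The main test was limma 3.58.1 (lmFit, and eBayes with a trend) on log2 of the value plus a pseudocount of 0.5, over genes with a value of at least 1 in at least 2 libraries, with group as the only term and 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over 12484 genes, with a threshold of 0.05. Log2 fold changes are on the scale of the value plus the pseudocount, which understates changes of low genes, and folds in the text are ratios of group means of the deposited values. Where a group had no read, a lower bound was computed from 3 reads in each of its libraries, a mean of 0.139 in the wild type and 0.157 in the knockout. Where a group had 1 to 3 reads, or all its reads in 1 library, read numbers, normalised counts or the ratio of read rates with an exact 95% interval are given. Intervals and floors cover counting error only. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom between 62.3 and 220, and each was counted as a sample. The closest pair was knockout C1 and C2 (62.3, and Pearson r = 0.982), against 204 and 220 for knockout SE with each of them and 139 in the wild type, and the labels do not exclude that the 3 knockout libraries hold a repeat of the same culture, in which case p-values could be too small.

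The tests, thresholds, 31 gene lists and most alternatives were fixed before the data were examined. Lists with at least 3 tested members (30) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. For lists, ranges and counts of fits over the alternatives cover refits at the preset correlation, and leave out the estimated correlation and fry. Members past the threshold were also counted with p-values adjusted over the list alone. The rule for named genes took Tnfaip6, the 10 genes with the largest log2 fold change in each direction and the 5 with the smallest p-value in each direction among called genes with non-overlapping groups and a mean of at least 5, and up to 4 members of each list with the smallest p-value. Predicted genes with clone-like names were left out of the largest changes. Some genes that the rule took are not reported here. Xist, Col1a1, Spp1 and members of the 6 lists added later were named after their values were seen. Genes near Tnfaip6 were compared with genes elsewhere by a two-sided Fisher's exact test. Library similarity was described by Pearson correlation and principal components without a test.

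Alternatives were TMM, quantile and median-of-ratios rescaling, pseudocounts of 0.1 and 1, no filter and a filter at 5, eBayes without a trend and with robust estimation, and leaving out each library in turn. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run as alternatives. A suffix block, a fit without both SE libraries, centring on each chromosome and a fit without chromosomes X and Y were added after the data were seen. Chromosome medians had 95% intervals from 1000 bootstrap draws. GC content and transcript length were corrected with splines of 5 degrees of freedom. Calculations used R 4.3.3 and Python 3.11.15.

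The tests were checked on simulated counts for the comparison of knockout with wild type, over 12484 genes with 200 changed genes in each of 5 rounds. At the replicate spread of these libraries, 4.78% of 2-fold, 58.5% of 4-fold and 94.8% of 8-fold changes were recovered, with 48 false calls over all rounds. A far larger share of genes was called in the real data (34.3%), and a smaller share of changed genes makes the adjusted threshold stricter. These recoveries therefore do not give the shares missed in the real data. Lists raised in the simulation were called in 5 of 5 rounds and unchanged lists in 0 of 150 camera tests. Simulated genes were drawn independently of each other, so these list results cannot show how often lists of correlated genes are called wrongly. In the real data, estimated correlations in the called lists ran from -0.166 (sex-linked genes) to 0.823 (collagens).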

Results

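Gene expression was measured by sequencing of poly(A) RNA from mesenchymal stem cells of mice, the adherent stromal progenitors that can form bone, fat and cartilage. The cells were wild type or lacked TSG-6, a secreted protein that binds hyaluronan and is encoded by Tnfaip6. The strain label names a Balb/c line with a 129S6 part for every sample. The table held 5 libraries, 2 from wild-type and 3 from knockout cells, although the short design text speaks of 2 biological replicates per cell type. Column names set the libraries apart as C1 and SE in the wild type and as C1, C2 and SE in the knockout, and the labels give no meaning for these suffixes. Reads assigned to genes numbered 25978244 in wild-type C1, 17986301 in wild-type SE, 21991615 in knockout C1, 26658725 in knockout C2 and 13605555 in knockout SE. Values are normalised counts, on the scale of CPM, given as mean ± SD with n = 2 wild-type and n = 3 knockout libraries. Nothing in the labels says which libraries came from separate animals or cultures, so p-values measure the spread between these libraries.

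The targeted gene was read first in every library. Tnfaip6 (ENSMUSG00000053475, chromosome 2, 52038009 to 52056686, plus strand, GRCm38) had normalised counts of 6.04 in wild-type C1 and 3.21 in wild-type SE, from 149 and 62 reads. In the knockout the values were 1.65 in C1, 2.38 in C2 and 1.36 in SE, from 35, 63 and 19 reads. Every knockout library was therefore below every wild-type library, with means of 1.80 ± 0.53 against 4.63 ± 2.0 and a log2 fold change of -1.13 (SE 0.37). This difference did not pass the threshold (limma, adjusted p = 0.0578), and across 19 alternative settings the adjusted p lay between 0.00943 and 0.364, past 0.05 in 4 of them. With the suffix as a block, chosen after the data were seen, the gene was called (log2 fold change -1.22, adjusted p = 0.00943), and it was also called with quantile normalization, without a variance trend and without both SE libraries. The labels do not say which part of the gene was deleted, and reads counted over the whole gene cannot show whether the remaining transcripts contained it.

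The comparison asked which transcripts differ in mesenchymal stem cells without TSG-6, a question the series title ties to stemness. Knockout and wild-type cells differed across a large part of the transcriptome. Of 12484 genes tested, 2150 were higher and 2129 lower in the knockout at an adjusted p under 0.05, together 34.3% of those tested. Changes of at least 2-fold made up 1956 of the higher and 1844 of the lower genes. Among the lower genes, 115 had no read in any knockout library, and 92 of the higher genes had no read in any wild-type library. Values of the groups did not overlap for 7336 genes (58.8%), where chance gives 20%. Pearson correlations of log2 values across genes lay between 0.946 and 0.982 for libraries of the same group and between 0.753 and 0.810 for libraries of different groups. The first principal component held 80.4% of the variance and parted the groups, and the second held 14.7% and parted the SE from the C libraries. Compared within the suffixes, C against C and SE against SE, 87.8% of all tested genes had the same sign in both, and the fold changes correlated across genes with r = 0.950. With the suffix as a block, chosen after the data were seen, 3530 genes were higher and 4038 lower. Without wild-type C1 the counts were 1134 and 594, without wild-type SE 1049 and 627, and without knockout C2 1461 and 1280.

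The largest rises included several secreted proteins. Sfrp2, a secreted Wnt modulator (ENSMUSG00000027996, chromosome 3, 83766321 to 83774316), rose from 0.438 ± 0.333 to 515 ± 114, a log2 fold change of 9.13 (SE 0.32, adjusted p = 4.34e-05). Gas6, a ligand of receptor tyrosine kinases (ENSMUSG00000031451, chromosome 8, 13465374 to 13494490), rose 554-fold to 1833 ± 290 (adjusted p = 4.34e-05). Dio3, an imprinted deiodinase that inactivates thyroid hormone, had 3 reads in the wild type and 14791 in the knockout, a rate ratio of 3517 with a 95% counting interval from 1203 to 17056. All 3 wild-type reads of Dio3 were in C1, the knockout values were 328, 82.8 and 403, and without single libraries the fold of means was 2232 or more, with no upper bound without wild-type C1. The haptoglobin gene Hp rose 391.8-fold, and the R-spondin receptor gene Lgr5 went from 0.205 ± 0.003 to 223 ± 121. Selenop, the selenium carrier of plasma, reached 3036 ± 1264, 244-fold above the wild type, and Gpx3, the extracellular glutathione peroxidase, reached 2028 ± 708, a 194-fold difference. The adipokine gene Adipoq rose from 0.168 ± 0.164 to 302 ± 380, with knockout values of 75.0, 741 and 90.4. Plin1, which coats lipid droplets, rose 494-fold (319.5 to 1089 without single libraries). No wild-type library had a read of Dpep1, a membrane dipeptidase, which was at least 650-fold higher in the knockout at a floor of 3 reads per library. Among genes with the smallest p-values in this direction, Bicc1 rose 180-fold and Plxdc2 rose 135-fold.

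The largest falls took several well-read transcripts to or near 0 reads. Crabp1, a retinoic acid binding protein (ENSMUSG00000032291, chromosome 9, 54764748 to 54773110), fell from 1026 ± 285 to 0.0648 ± 0.0155, a log2 fold change of -10.80 (SE 0.30, adjusted p = 4.34e-05). The matrix proteoglycan gene Dcn (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143) had 36130 reads in the wild type and 1 in the knockout, and its wild-type mean was 791 ± 351. Areg, an EGF-receptor ligand, had a wild-type mean of 259 ± 83.2 and no knockout read, and was at least 1653-fold lower. The same held for Gpr149, at least 1072-fold lower, and for Tspan11, at least 1065-fold lower. Klra4 was at least 1648-fold lower, but it belongs to a family of similar natural killer cell receptor genes among which reads can be split. Msln, a mesothelial surface protein, fell 2078-fold, and Tgfbi, a secreted matrix adhesion protein induced by TGF-beta, fell 1089-fold (757 to 1674 without single libraries). Dpysl3, a cytoskeletal regulator of axon growth, fell 637-fold. Bmp2, an inducer of bone formation, fell from 191 ± 26.2 to 0.107 ± 0.060, with a log2 fold change of -8.30 (SE 0.29).

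**Figure D1:**
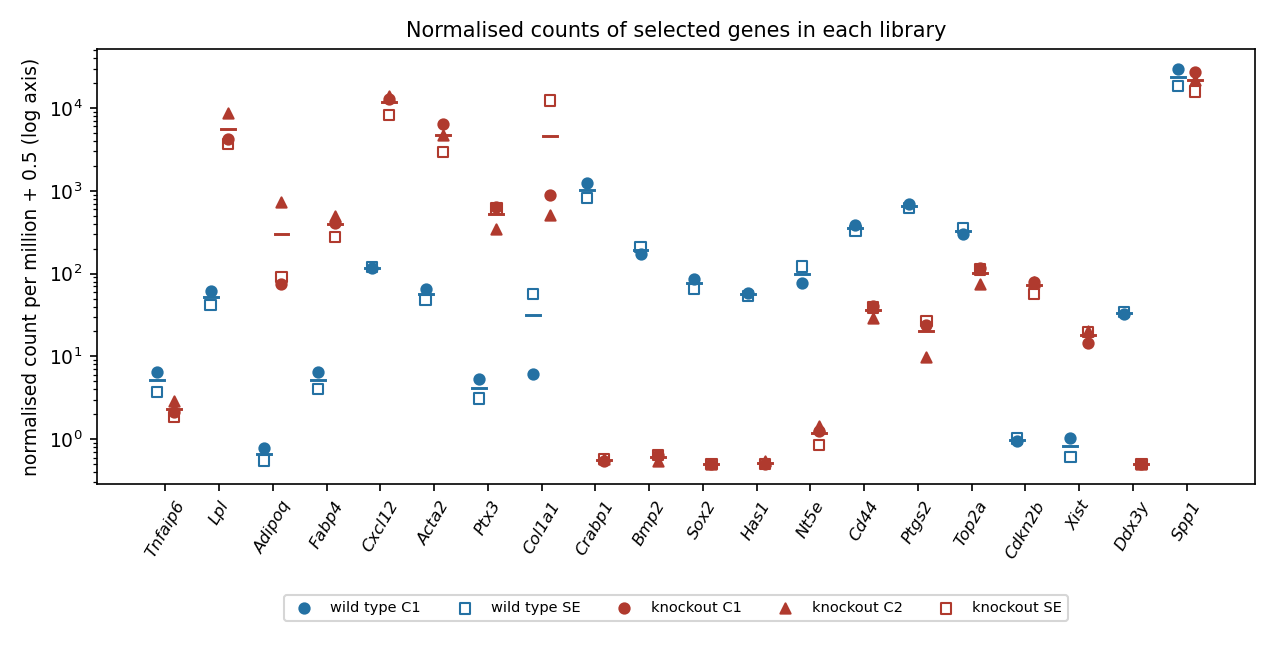
Normalised counts (CPM scale) plus 0.5 (log axis) of 20 genes in each of the 2 wild-type (blue) and 3 knockout (red) libraries, with open squares for the SE libraries and bars at the group means. Crabp1, Sox2, Has1 and Ddx3y lie near the bottom in every knockout library, Lpl and Cxcl12 are higher in all 3, and the Tnfaip6 means differ 2.57-fold.

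Most tested genes of the fat lineage rose. Of 18 adipogenic genes tested, 13 rose and 0 fell, also 13 and 0 when adjusted over the list alone, and the list was higher as a set (limma camera, adjusted p = 3.26e-05; adjusted p = 0.736 with an estimated correlation). Lpl, which releases fatty acids from lipoproteins, rose from 51.0 ± 14.0 to 5506 ± 2749 (log2 fold change 6.66, SE 0.43). Fabp4, a fatty acid carrier of adipocytes, rose 83.0-fold, and Cebpa, a master regulator of adipocyte formation, rose 53.7-fold. Osteogenic genes went both ways, with 5 higher and 4 lower of 15 (6 and 4 adjusted over the list alone; camera adjusted p = 0.501, in a range from 0.0272 to 0.863 over all alternatives). Alkaline phosphatase, Alpl, rose from 0.0811 ± 0.115 to 79.1 ± 50.2, and Postn, an extracellular matrix protein of bone surfaces, was at least 383-fold higher, while Bmp2 fell and Dmp1, an osteocyte gene, went from 456 reads to 2. Spp1, which encodes osteopontin and was named after its values were seen, held 1.62% to 2.81% of the summed values of each library and was not called different, at 24021 ± 7900 and 21742 ± 5756 (adjusted p = 0.886). Of 11 chondrogenic genes, 5 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.833). Matn4, a cartilage matrix protein, was at least 93.2-fold higher, whereas Col11a1 went from 2478 reads to 2 and Sox5, a chondrocyte transcription factor, fell 23.2-fold.

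Contractile genes also rose, and most collagens that passed the test were higher. Of 24 actin cytoskeleton and contractile genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 3.26e-05, and adjusted p = 0.739 with an estimated correlation). Acta2, smooth muscle alpha-actin, rose from 56.0 ± 12.1 to 4732 ± 1743 (log2 fold change 6.33, SE 0.38), and Actg2 rose 220-fold, although actin genes are similar enough for reads to be shared. Mylk, the myosin light chain kinase of smooth muscle, rose 84.7-fold (63.4 to 127 without single libraries) and Myl9 rose 69.7-fold. Of 18 collagens, 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0252, and adjusted p = 0.752 with an estimated correlation). Col12a1 rose 31.6-fold (20.2 to 37.8 without single libraries), Col6a2 rose 7.39-fold and Col1a2 rose 47.8-fold (21.8 to 108 without single libraries) with a wide spread, at 4332 ± 4089. Collagens also moved with the suffix, and Col1a1, singled out after its values were seen, had normalised counts of 5.55 in wild-type C1 and 56.1 in wild-type SE against 882, 506 and 12333 in knockout C1, C2 and SE. At the preset correlation, the collagen call was also lost without wild-type C1 and without knockout SE (camera adjusted p = 0.0991 without knockout SE).

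Hyaluronan genes, the matrix that TSG-6 binds, changed in both directions. Of 17 genes for hyaluronan and its partners, 4 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.522). Has1, a hyaluronan synthase, went from 2452 reads to 1, a rate ratio of 3438 with a 95% counting interval from 616 to 135829, and a fold of means of 2930 or more without single libraries. The hyaluronan receptor gene Cd44 (chromosome 2, 102811141 to 102901665) fell from 355 ± 42.4 to 35.9 ± 6.36, a 9.89-fold difference. Ptx3, a pentraxin of the hyaluronan-rich matrix, rose from 3.71 ± 1.58 to 529 ± 161, and Itih5, of the inter-alpha-trypsin inhibitor heavy chain family, was at least 123-fold higher. Of 21 matrix proteases and inhibitors, 8 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.195, in a range from 0.0204 to 0.337 over all alternatives). Mmp23 rose 188-fold, while Mmp3, a stromelysin, fell 61.5-fold (41.0 to 105 without single libraries), Mmp10 went from 222 reads to 1, and Plat, the tissue plasminogen activator, fell 6.61-fold.

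Most markers of mesenchymal stem cells and regulators of stemness that passed the test fell, without either list passing as a set in the main test. Of 14 surface markers, 5 fell and 0 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.113, in a range from 0.0118 to 0.649 over all alternatives). Nt5e, the ectonucleotidase CD73, fell from 99.4 ± 31.1 to 0.685 ± 0.299, Alcam went from 1624 reads to 10, all of them in knockout C2, and Nes, the intermediate filament nestin, fell 20.3-fold. Nes was counted among the 5 that fell, although an intermediate filament is not a surface protein. Of 13 stemness and self-renewal regulators, 6 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.356). Sox2, a pluripotency and neural stem cell factor, had a wild-type mean of 75.4 ± 15.0 and no knockout read, and was at least 482-fold lower. Hmga2 fell 5.74-fold and Klf4 fell 5.16-fold, while Snai2, a mesenchymal transcription factor, rose 5.47-fold. The log2 fold changes were -2.41 for Klf4 and 2.44 for Snai2. Tested genes in the same stretch of the chromosome had medians of -1.32 around Klf4 and 0.85 around Snai2. Part of both changes was therefore shared with their surroundings. Hmga2 (log2 fold change -2.54) fell against the median of its stretch (0.33). The position-specific Hox and limb genes were split, with 5 higher and 6 lower of 24, the same counts adjusted over the list alone (camera adjusted p = 0.560). Hoxa11 went from 1050 reads to 2 and the limb factor gene Tbx5 was at least 80.9-fold lower, whereas Hoxb7 rose 21.97-fold. Of 10 imprinted growth genes, 6 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0723, in a range from 0.0272 to 0.274 over all alternatives). Igf2 went from 4 reads, all in wild-type SE, to 944, Mest rose 12.7-fold and Ndn rose 6.87-fold.

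Genes of cell division were lower in the knockout. Of 30 mitosis and G2/M genes, 19 fell and 0 rose (22 and 0 adjusted over the list alone; camera adjusted p = 3.26e-05, and adjusted p = 0.752 with an estimated correlation). Top2a, which untangles DNA, fell from 327 ± 41.0 to 101 ± 23.4 (log2 fold change -1.71, SE 0.27), the mitotic kinase gene Aurkb fell 3.69-fold, and Ccna2 fell 3.29-fold. Of 30 DNA replication and G1/S genes, 17 fell and 1 rose (21 and 1 adjusted over the list alone; camera adjusted p = 9.87e-05, and adjusted p = 0.752 with an estimated correlation). Mcm7, part of the replicative helicase, fell 3.07-fold, and the cyclin gene Ccne2 fell 4.56-fold. Cell cycle inhibitors and p53 targets went both ways, with 8 higher and 2 lower of 25 (8 and 5 adjusted over the list alone; camera adjusted p = 0.402, with a median of -0.18 and a mean of 0.53 on the log2 scale). Cdkn2b, a cyclin-dependent kinase inhibitor, rose from 0.482 ± 0.051 to 71.6 ± 13.01, and its neighbour Cdkn2a rose 49.1-fold (32.2 to 103 without single libraries). Sesn1, a p53 target, rose 4.05-fold. In windows of about 50 tested genes, the median log2 fold change was 1.47 around Sesn1 and -1.04 around Ccne2. The genes themselves had 1.97 and -2.18, so much of both changes was shared with their surroundings. Cdkn2b and Cdkn2a rose against the median of their window (-0.47).

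Immune genes did not move as one group. Of 16 MHC and antigen processing genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.0153, and adjusted p = 0.752 with an estimated correlation). Cd74, the invariant chain, was at least 47.9-fold higher and Tap2, a peptide transporter, rose 4.29-fold. The list also holds H2 genes, whose reads can be split among near-identical copies and depend on strain. Of 25 interferon-stimulated genes, 6 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0236, and adjusted p = 0.752 with an estimated correlation). Among the members that fell, the antiviral gene Rsad2 fell 13.6-fold (10.4 to 32.0 without single libraries). At the preset correlation, the interferon call was lost without knockout C2 (adjusted p = 0.111) and in 3 other settings, in a range from 0.00135 to 0.111 over all refits. Of 15 NF-kB and inflammatory mediators, 3 rose and 6 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.389). Prostaglandin genes were among those that fell: Ptgs2, or cyclooxygenase-2, went from 654 ± 50.03 to 19.7 ± 9.07 and Ptges fell 10.1-fold. Il11 fell 60.9-fold, to 6 knockout reads, and the fold lay between 40.6 and 350 without single libraries.

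Immunomodulatory and trophic factors of stromal cells were higher as a set, and the chemokine list did not pass. Of 22 such factors, 9 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0181, and adjusted p = 0.736 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, rose from 42.3 ± 24.3 to 2320 ± 1074, Kitl, the ligand of the Kit receptor, rose 17.0-fold, Gdf15 rose 25.3-fold and Tgfb2 rose 9.25-fold. Of 9 chemokines, 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.121, in a range from 0.00623 to 0.436 over all alternatives). Cxcl12, which retains blood stem cells in marrow (chromosome 6, 117168535 to 117181367), rose from 117 ± 3.70 to 11680 ± 3099 (log2 fold change 6.59, SE 0.34). Ccl9 rose 17.2-fold and Cxcl14 rose 19.4-fold (12.0 to 24.2 without single libraries). Of 22 Wnt pathway genes and targets, 11 rose and 5 fell, also when adjusted over the list alone. The list lay just short of the threshold (camera adjusted p = 0.0553, in a range from 6.16e-05 to 0.0960 over all refits at the preset correlation, and adjusted p = 0.752 with an estimated correlation). The Wnt agonist gene Rspo2 rose 44.6-fold and Rspo3 went from 1 read to 1217, whereas Tcf7, a Wnt transcription factor, fell 572-fold (381 to 985 without single libraries). Of 25 TGF-beta and BMP response genes, 7 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.585, with a median of 0.50 and a mean of -0.22 on the log2 scale). Bmp4 rose 19.9-fold and Smad6, an inhibitor of BMP signalling, rose 7.10-fold.

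**Figure D2:**
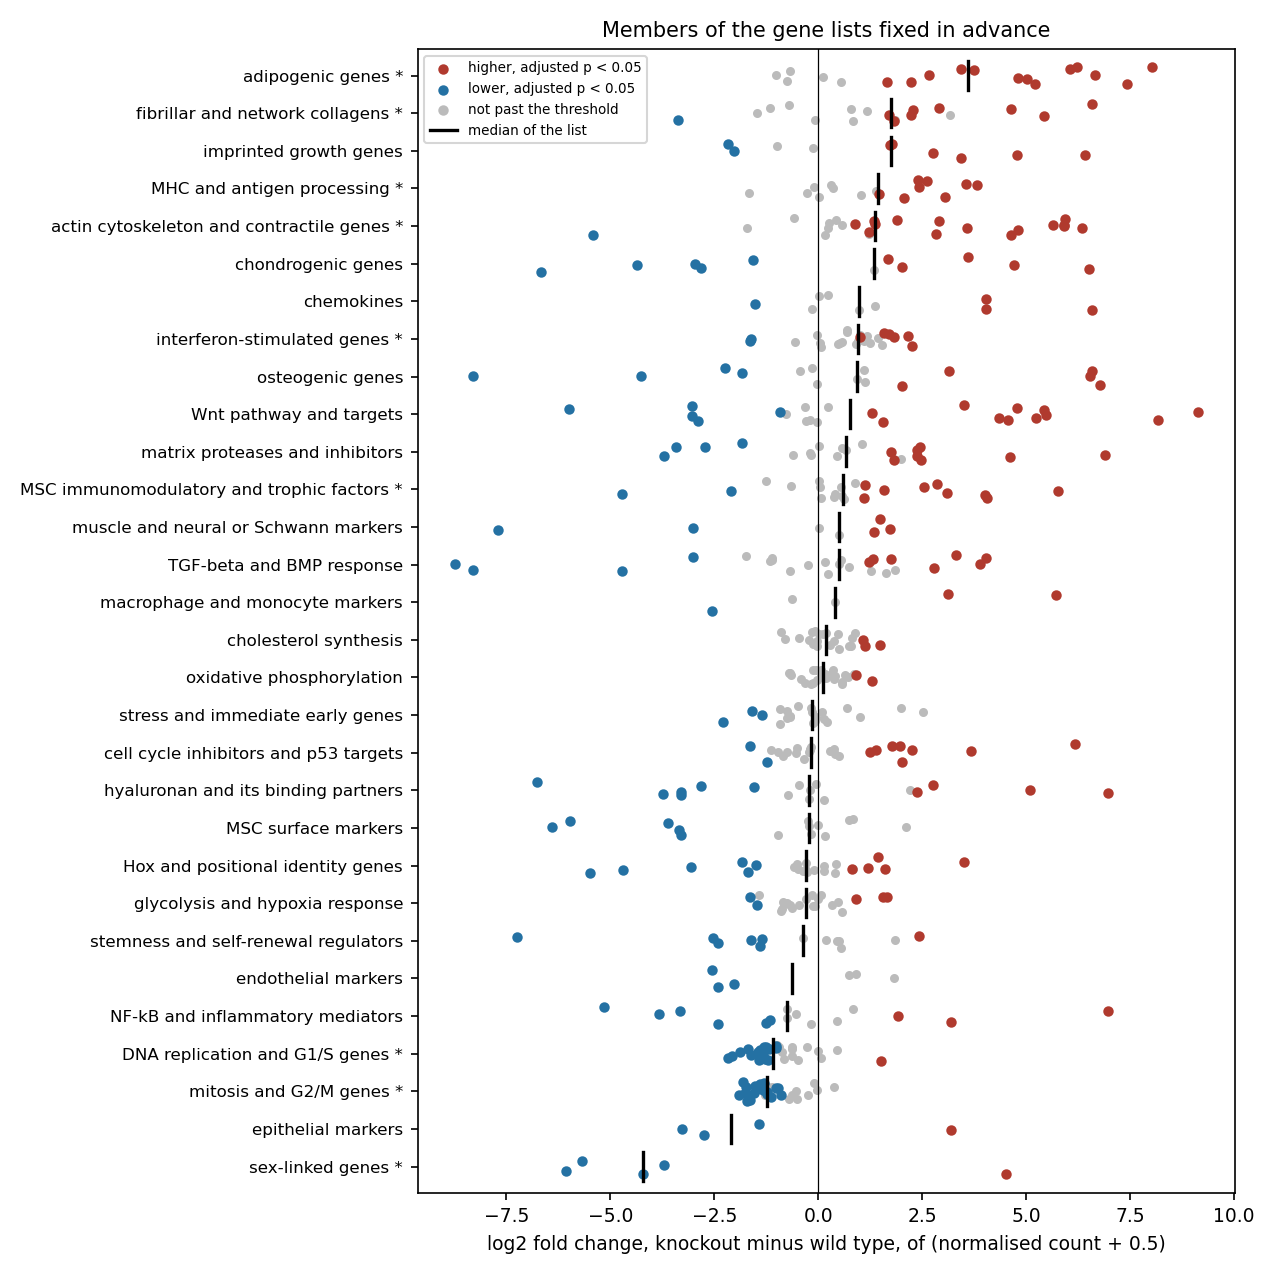
Log2 fold changes (knockout minus wild type, of normalised counts plus 0.5) of the members of 30 gene lists, one point per gene, red or blue where the adjusted p was under 0.05, with a bar at the median of each list. An asterisk marks the 9 lists past an adjusted p of 0.05 with camera's preset correlation of 0.01, 0 of which passed with an estimated correlation.

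Few metabolic and stress genes passed the test. Of 26 oxidative phosphorylation genes, 2 rose and 0 fell (camera adjusted p = 0.389). Adjusted over the list alone, limma called 0 of them, with 5 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 2. The genes called by limma over all tested genes were Atp5o, which rose 2.46-fold, and Sdhc, which rose 1.91-fold, and both calls were lost without wild-type SE, knockout C1 or knockout C2, and that of Sdhc also without wild-type C1. Both calls were also lost with each library centred on the median of each chromosome (adjusted p = 0.462 and 0.210). Over all alternatives the adjusted p lay between 0.000236 and 0.462 for Atp5o and between 0.00126 and 0.210 for Sdhc. Of 23 glycolysis and hypoxia genes, 3 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.559). P4ha2, a collagen prolyl hydroxylase, rose 3.21-fold, and Adm, a vasodilator peptide, rose 2.99-fold. Of 23 cholesterol synthesis genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.258, in a range from 0.0142 to 0.715 over all alternatives), among them Nsdhl, which rose 2.84-fold. Of 22 stress and immediate early genes, 3 fell and 0 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.389, in a range from 0.0142 to 0.940 over all alternatives), with Jun down 3.03-fold.

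Few markers of other cell types were in the table, and those that passed the test went both ways. Of 5 macrophage and monocyte markers tested, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.522). Lyz2 rose from 0.0811 ± 0.115 to 30.3 ± 5.20 and Csf1r rose to 6.34 ± 2.93, while Cd14 fell 6.10-fold. S100a8 and Camp, the 2 lymphocyte, neutrophil and erythroid markers tested, both rose, also adjusted over the list alone, to 1.497 ± 0.404 and 1.74 ± 1.29 from no read. The Camp call was lost without either wild-type library, with an adjusted p of 0.118 without C1 and 0.116 without SE, in a range from 7.56e-05 to 0.118 over all alternatives. Of 6 endothelial markers, 3 fell and 0 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.482), and Flt1 fell from 3.13 ± 0.91 to 0.109 ± 0.035. Of 4 epithelial markers, 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.322). Krt19 fell 7.47-fold and Krt18 was at least 30.5-fold lower, while Krt7 went from 5 reads, all in wild-type SE, to 316. Of 7 muscle, neural and Schwann markers, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.833, with a median of 0.50 and a mean of -0.80 on the log2 scale). Gap43, a growth-cone protein, went from 4987 reads to 1, and Tubb3, neuronal beta-tubulin, from 170 reads to 2.

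Sex-linked genes separated the groups in every library. Of 5 sex-linked genes, 4 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.736 with an estimated correlation). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d together had 1932 and 1334 reads in the wild-type libraries and 0 in each knockout library, and Ddx3y was at least 209-fold lower. Xist, the RNA that coats the inactive X chromosome, was named after its values were seen and had normalised counts of 0.527 and 0.104 in the wild type and 14.1, 19.6 and 19.1 in the knockout. The list call was lost with the suffix as a block (adjusted p = 0.0759) and with a filter at 5 (adjusted p = 0.0697), in a range from 0.000155 to 0.0759 over all alternatives that kept the list. Without genes on chromosomes X and Y, a setting chosen after the data were seen, 2052 genes were higher and 2092 lower.

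Fold changes also differed between chromosomes. Genes on chromosome 16 had a median log2 fold change of 0.82 (95% bootstrap interval 0.76 to 0.88), with 84.3% of 388 genes above 0, and genes on chromosome 12 had a median of 0.60 (0.50 to 0.69). Genes on chromosome 4 had a median of -0.58 (-0.69 to -0.51) and those on chromosome 11 a median of -0.38 (-0.45 to -0.31). Some shifts covered a chromosome only in part, with medians of windows of about 50 genes from -1.32 to 0.09 on chromosome 4 and from -0.10 to 1.47 on chromosome 10, against 0.65 to 1.08 on chromosome 16. On chromosome 16, 155 genes rose and 12 fell, and on chromosome 4, 79 rose and 238 fell. The SD of the 19 autosome medians was 0.380 between the groups, 0.0439 between the wild-type libraries and 0.0405 between knockout C2 and C1. With each library centred on the median of each chromosome, chosen after the data were seen, 1966 genes were higher and 1475 lower, so that 57.1% of the calls were rises against 50.2% before. Around Tnfaip6, 44 of 147 genes within 20 Mb were called (29.9%) against 34.3% of genes elsewhere, an odds ratio of 0.818 (two-sided Fisher's exact test, p = 0.294). The odds ratio was 1.31 within 10 Mb (Fisher's exact p = 0.488) and 0.791 within 40 Mb (Fisher's exact p = 0.0371). On chromosome 2 as a whole, 145 of 990 genes were called higher and 147 lower (14.65% and 14.85%). A comparison with the whole genome therefore cannot set the surroundings of Tnfaip6 apart from the rest of chromosome 2, and neighbouring genes are not independent.

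**Figure D3:**
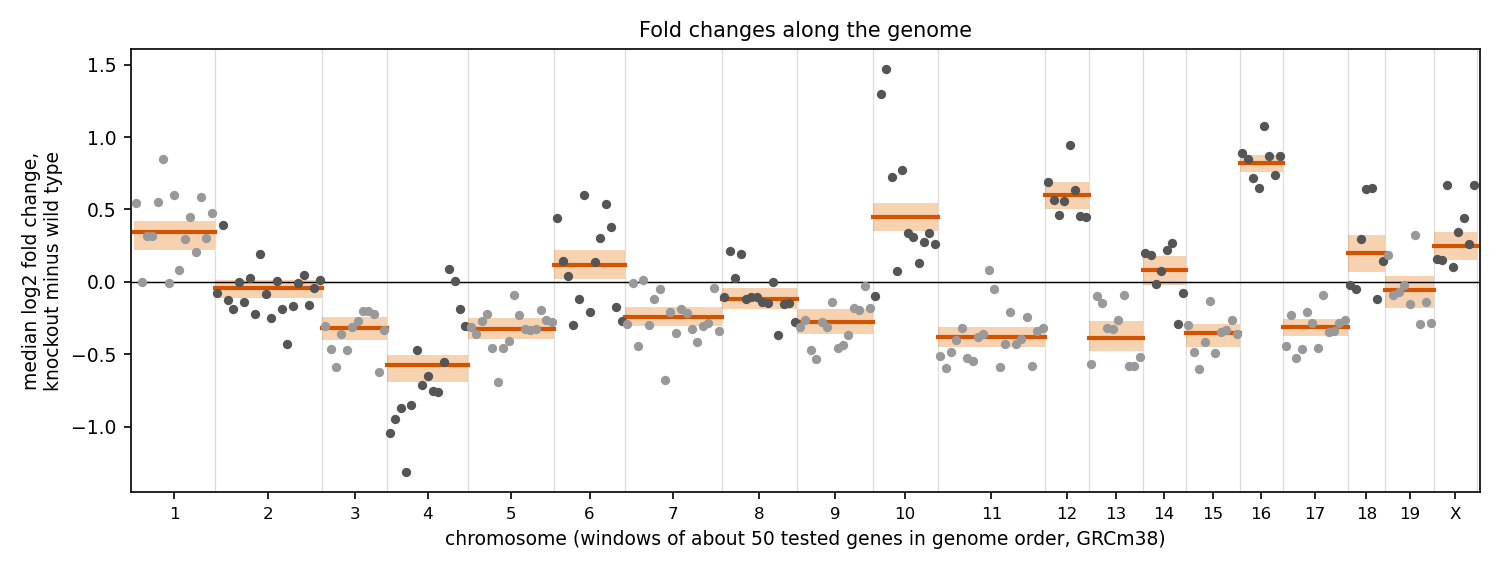
Median log2 fold change (knockout minus wild type) in windows of about 50 tested genes in genome order (points), with the chromosome medians (lines) and their 95% bootstrap intervals (bands). All 8 windows of chromosome 16 and all 8 of chromosome 12 lie above 0, while 13 of 15 windows of chromosome 4 lie below it.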

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

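The suffix block, the fit without both SE libraries, centring on each chromosome and the fit without chromosomes X and Y were chosen after the data were seen. Of 123 called named genes, 118 stayed past the threshold under every alternative that kept them, none changed sign, and Atp5o, Sdhc, Camp, Col1a1 and Hspa5 lost the call somewhere. Most of these genes were picked for small p-values or large changes in these same data, so their stability does not carry over to all called genes. Of the 4279 called genes, 3197 were shared without knockout C1 and 2693 without knockout C2. Rescaling by TMM moved nothing, because the deposited values already had that scaling. The numbers of higher and lower genes were within 1.5 times of 2150 and 2129 under the other scalings, pseudocounts, filters and variance models, with 2038 and 2053 by edgeR and 2600 and 2236 by DESeq2, and 4044 and 4186 of the 4279 called genes were shared. Leaving out single libraries gave between 1049 and 2332 higher and between 594 and 2632 lower genes, and between 9 and 14 lists. The lowest counts came without wild-type C1 (1134 and 594, 65.6% higher) and without wild-type SE (1049 and 627, 62.6% higher), where the lone wild-type library was assumed to vary like the knockout libraries and fewer samples entered the fit. The suffix block gave 3530 higher and 4038 lower genes, and removes the difference between SE and C libraries from the residual spread. By the replicate numbers of the sample titles, no paired analysis was possible because the column names do not carry them, so that planned block was not run, and the suffix block was added in its place. Of the 9 lists past the threshold, 0 passed with camera's estimated correlation, where 0 lists had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 18. The 9 lists kept their call in 167 of 175 fits of a list under an alternative, and lists short of the threshold passed it in 27 fits: Wnt in 8 (lowest adjusted p = 6.157e-05), chemokines in 4 (0.006229), imprinted genes in 4 (0.02716), osteogenic genes in 3 (0.02724), matrix proteases in 3 (0.02043), surface markers in 2 (0.01182), cholesterol synthesis in 2 (0.01417) and stress genes in 1 (0.01417). The log2 fold change of Tnfaip6 passed the threshold with quantile normalization (-1.305, adjusted p = 0.0399), without a variance trend (-1.125, adjusted p = 0.0495), with the suffix block (-1.223, adjusted p = 0.00943) and without both SE libraries (-1.394, adjusted p = 0.0296), in a range of adjusted p from 0.00943 to 0.364, and lay between -1.534 and -0.7167 when single libraries were left out. The odds ratio of called genes near Tnfaip6 turned to 1.309 within 10 Mb and passed the threshold at 0.7912 within 40 Mb. That lower share cannot be set apart from the level of chromosome 2 as a whole. Spp1, not called in any setting, lay between -0.481 and 0.2025 without single libraries and at 0.2674 with centred chromosomes. Among lists that did not pass, some turned direction, and ranges of the adjusted p without single libraries cover all 5 such fits, turned or not. Chondrogenic genes turned with a filter at 5 (adjusted p = 0.7199), by edgeR (0.9412), by DESeq2 (0.6889) and without knockout SE (0.6098, range 0.36 to 0.9876). Muscle, neural and Schwann markers turned in the same first 3 settings (0.7199, 0.4694 and 0.6889), with centred chromosomes (0.9656) and without knockout C1 (0.6863) or C2 (0.9795, range 0.103 to 0.9795). The TGF-beta and BMP response turned by edgeR (0.7743) and DESeq2 (0.7265). Hyaluronan and Hox genes turned without both SE libraries (0.8883 and 0.6874) and without wild-type SE (0.8281, range 0.4929 to 0.8497, and 0.6806, range 0.4729 to 0.8838). Cholesterol synthesis turned without wild-type C1 only (0.7149, range 0.01417 to 0.7149, where the lowest kept the main direction), endothelial markers without either wild-type library (0.452 and 0.1691, range 0.1575 to 0.5874), oxidative phosphorylation without wild-type SE (0.6207, range 0.07766 to 0.6508) and glycolysis and hypoxia without knockout SE (0.9408, range 0.4154 to 0.9408). Where no other reason is given, the cause was not tested. In the simulation, 2-fold changes were mostly missed (4.78% recovered), but fewer genes changed there than were called here, which made its threshold stricter. That share does not carry over to these data, and genes not called can still differ.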

Other observations

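Gene groups beyond the lists fixed in advance were assembled after the values were seen, so their tests describe a pattern already noticed. The tests of the sex-linked genes and the count over splits were likewise chosen only after the result was seen. Of 15 perivascular marrow niche genes, 9 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.000165, and adjusted p = 0.155 with an estimated correlation). Besides Cxcl12, Kitl, Gas6, Hp and Lpl, which other lists or rules had already named, the transcription factor gene Ebf1 rose 72.7-fold (52.99 to 116 without single libraries) to 234 ± 19.8, Esm1 rose 50.3-fold and Angpt1 rose 6.10-fold, while the BMP antagonist gene Grem1 fell 23.7-fold (19.3 to 41.0 without single libraries) from 354 ± 68.1. Of 12 complement components and regulators, 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00115, and adjusted p = 0.163 with an estimated correlation). C1ra rose 11.4-fold, the C1 inhibitor gene Serping1 rose 8.35-fold and Cfd was at least 38.4-fold higher, while Cd55, which protects cells from complement, was at least 10.6-fold lower.

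Of 9 axon and neurofilament genes, 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 3.52e-05, and adjusted p = 0.155 with an estimated correlation). Sox2, Gap43, Dpysl3 and Tubb3 of this list had already been named. Sox2 is a neural stem cell factor and neither an axon nor a neurofilament gene, but it was counted in the list. The neurofilament genes Nefl and Nefm had wild-type means of 77.7 ± 23.9 and 74.9 ± 17.7 and no knockout read, at least 496-fold and 479-fold lower. Cntn1, a neural adhesion gene, was the member that rose and was at least 73.6-fold higher. Of 18 endoplasmic reticulum chaperones and folding enzymes, 8 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.00459, and adjusted p = 0.217 with an estimated correlation). Dnajc3 fell 2.84-fold, and Hspa5 fell from 4376 ± 589 to 1424 ± 234, a call lost without wild-type C1 (adjusted p = 0.0627, in a range from 3.3e-06 to 0.0627 over all alternatives). Of 73 ribosomal protein genes, 11 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.000325, and adjusted p = 0.717 with an estimated correlation). Selenoprotein and antioxidant genes went both ways, with 8 higher and 5 lower of 23, the same counts adjusted over the list alone (camera adjusted p = 0.257), and Gclc and Nqo1 fell 8.51-fold and 13.6-fold.

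Of the 10 splits of the 5 libraries into 2 and 3, 1 gave as many called genes as the real split, namely the real one, with 4279 against a highest of 0 among the others (limma, with up to 1559 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Every other split puts wild-type and knockout libraries in the same set. The group difference then adds to the residual spread and lowers the calls, so the 0 does not measure chance.

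Chromosomes were shifted between knockout and wild type, some of them only in part, with autosome medians from -0.58 on chromosome 4 to 0.82 on chromosome 16, and an SD of these medians of 0.380 that 9999 rotations of gene order along the genome reached rarely (permutation p = 3e-04). Correction for GC content and transcript length left 102.6% of that SD, which argues against such a bias. Of all tested genes, 84.3% lay above 0 on chromosome 16 (95% bootstrap interval 80.7% to 87.6%) and 28.3% on chromosome 4 (25.03% to 31.5%). The share was 45.4% on the other autosomes. These shares were chosen after the values were seen, for the autosomes with the highest and lowest medians. On both, the shift was spread over many genes. A few strongly changed genes hardly move a median, so the shares restate the shift and are no separate test of that explanation. Across the 19 autosomes, the median of 355 housekeeping genes followed the median of the other genes on their chromosome (Pearson r = 0.9559, permutation p = 1e-05, the smallest that the permutations can give; Spearman rho = 0.875, p = 3e-05; adjusted 2e-05 and 3e-05; r = 0.921 without chromosomes 16 and 12), as copy numbers of chromosomes or large parts of them that differ between the groups would give. Such a difference in copy number is a candidate explanation and a hypothesis only, since no DNA was measured and a broad regulatory cause was not tested, and it may add to the counts of called genes apart from the loss of TSG-6.

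The sex-linked genes differed in every library, with 3266 reads of 4 Y-linked genes in the wild type and 0 in the knockout. Reads shared between Y-linked genes and their X-linked copies are argued against by these 0 reads, because the X-linked copies were read in every knockout library. The knockout mean of these copies was 90.9% of the wild-type mean. Their summed values were 212.7 and 222.0 in knockout C1 and C2 against 290.1 in wild-type C1, and 392.9 in knockout SE against 316.7 in wild-type SE. The copies were thus lower in the knockout among the C libraries and higher among the SE libraries. For male cells mixed into the knockout libraries the test was void and no verdict is given, because such cells would shrink the difference and the upper 95% limit of the knockout Y-linked rate, 0.06552% of the wild-type rate, restates the same 0 reads. The lowest knockout value of Xist was 26.77-fold above the highest wild-type value, which is consistent with cells of different sex in the 2 groups, a hypothesis found on the same data. The labels give no sex, so a loss of chromosome Y stays open for the Y-linked genes alone, and effects of sex or of separate cell isolates cannot be separated from those of the knockout by this design.

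The SE libraries differed from the C libraries alike in both groups, with r = 0.753 across genes between the wild-type and the knockout difference, and genes are not independent replicates. With group in the model, 2166 genes were higher and 1932 lower in SE. Collagens were higher in SE (13 of 18 past the threshold), and ribosomal protein genes were lower (59 of 73), although no list passed with an estimated correlation (lowest adjusted p = 0.612). The difference rose with transcript length (r = 0.455 with log2 length in the wild type and 0.552 in the knockout), and with GC content and length corrected the median log2 difference went from 2.03 to 1.20 for collagens and from -0.59 to -0.12 for ribosomal protein genes, so a length trend may hold much of the latter. After correction for GC content and transcript length r was 0.6162, 81.9% of its value, and after thinning every library to 13610000 reads it was 0.7404, so neither that bias nor the lower depth of the SE libraries accounts for the whole pattern. What SE and C stand for is not given in the labels, and no biological explanation was tested.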
